A study of Schizosaccharomyces pombe with 12 samples.

How the data were processed

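Total RNA of 12 samples of Schizosaccharomyces pombe (3 strains in 4 conditions) was hybridised as biotinylated cRNA to Affymetrix Yeast Genome 2.0 arrays, 1 colour and 1 array per sample, per the labels. All strains are heterothallic, leu1-32 and ura4-D18, and each deletion was made with ura4, per the labels. The design text says that cells were grown in quadruplicate and that aliquots of each strain went to the 4 conditions, which can mean 1 culture or several, and the labels give no replicate numbers. Each strain and condition has 1 array. The samples are not said to be separate cultures, so p-values measure only the spread between these arrays.

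The authors' processed values are probe set intensities made with RMA in Affymetrix Expression Console 1.1, per the submitters' processing notes. The deposited intensity values run from 2.9 to 20293 and are on a linear scale, so log2 was taken of them. The design fixed before the data were examined had assumed log2 values. RMA corrects background, quantile-normalizes over all probes of an array and summarises probes, so total differences in RNA content between samples are removed and low signals are compressed. The background, normalization and summary settings are not given in the sources used here. All 12 value columns were used, and the number of unused ones is 0.

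The table holds 10928 probe sets. Of these 213 are control probe sets, 5538 carry a gene name in the platform annotation, and 5177 others have none. The annotation was matched to the RefSeq gene table of S. pombe, 2914 probe sets by gene ID and 3 by symbol, giving 2917 probe sets with exactly 1 gene and 2899 genes. 14 genes have several probe sets, which were tested separately. For a gene with several probe sets the text gives the one with the smallest p and says where they disagree. 20 probe sets shared by several S. pombe genes were left out of the tests, as were 2601 named probe sets of genes outside the S. pombe table, which served as the background level. No coordinates are given, since no build is named for the array.

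Tests were run in R 4.3.3 with limma 3.58.1 on the log2 values, with empirical Bayes moderation and an intensity trend, and Benjamini-Hochberg adjustment over 2917 probe sets. A probe set was called at an adjusted p under 0.05. Mutants against WT over all conditions, slm9D against hip1D and the 4 stress responses came from a fit with strain and condition as terms (6 residual degrees of freedom). Mutants against WT within a condition came from 8 means (4 residual degrees of freedom), with slm9D and hip1D as the 2 arrays of the mutant group. The differences of the mutants' responses from the WT response came from 8 means and a term for slm9D against hip1D (3 residual degrees of freedom). In the last 2 fits the lone WT array of a condition is assumed to vary as the mutant arrays do. Where a probe set was not above background (the 95th percentile of the outside probe sets) on any WT array of a comparison, the fold is given as a lower bound with the background in place of the dimmer signals.

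Before the data were examined, 22 gene lists were fixed, of pathways, complexes, cell cycle groups and chromosome regions. 21 had members among the tested probe sets, and the list of Tf2 retrotransposons had 0, since its probe set is shared by several genes. Each list was tested in each of 14 comparisons with limma's camera at a preset correlation of 0.01, giving 294 tests adjusted together. Of these 123 passed. With an estimated correlation 0 passed after adjustment, the smallest adjusted p being 0.419, and 21 had an unadjusted p under 0.05. Named genes followed a rule fixed before the data were examined. It takes slm9, hip1 and ura4, then up to 10 called probe sets with the largest positive and 10 with the largest negative difference per comparison, with the same sign in all strains or both mutants compared, and up to 4 members with the smallest p of each list described. The genes of the plots and those followed across comparisons come from that set. Their values in further comparisons, such as zym1 levels, were chosen after the first results were seen.

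The fits were tested on simulated data drawn on 2917 probe sets with 200 changed genes of 3 fold sizes. Mutants against WT over all conditions recovered 92.5% of the changes of 1.5-fold and 100% of those of 2-fold, with 3.9% of calls false. Mutants against WT in unstressed cells recovered 100% of both, with 5.7% of calls false, above the nominal 5%. The comparison of 40 °C then H2O2 with H2O2 alone recovered 70.1% and 97%, with 3.8% false, and its interaction 94% and 100%, with 3.9% false. Noise was drawn as independent normal values with the fitted spread, without error shared by the arrays of a culture. The shares thus hold only under the assumptions of the fits. The simulated WT arrays vary as the mutants do, so the simulation says nothing about a fault of a single WT array.

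Alternatives were a filter on dim probe sets, quantile normalization repeated on S. pombe probe sets alone, a shift of each array to equal medians of the outside probe sets, moderation without trend, a 2-fold threshold, leaving out probe sets that can match several transcripts, other strain terms, fewer arrays in the fit and leaving out arrays in turn. Leaving out the WT array after H2O2 alone was added after the data were seen. No rescaling moved the median of all S. pombe probe sets by more than 0.1 in any comparison. Figures were drawn with matplotlib 3.10.9.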

Results

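The data are 12 microarrays of fission yeast (Schizosaccharomyces pombe), 1 for each combination of 3 strains and 4 conditions. The strains were a wild type (WT), a deletion of slm9 (slm9D) and a deletion of hip1 (hip1D). Both genes encode subunits of HIRA, a conserved chaperone complex that deposits histones on DNA. Cells grown to log phase at 32 °C in rich YES medium were left unstressed, held at 40 °C for 1 h, treated with 25 mM hydrogen peroxide (H2O2) for 1 h, or held at 40 °C for 1 h and then treated with 25 mM H2O2 for 1 h. The labels call the 40 °C step a priming stress, and the series title puts the question as the part HIRA plays in the response to a low-dose stress. Of the probe sets, 2917 had exactly 1 S. pombe gene (2899 genes), and 2906 of these had a mean signal above the 95th percentile of the probe sets assigned to genes outside the S. pombe table (log2 3.74). The median log2 intensity of the S. pombe probe sets lay between 9.46 and 9.57 on 11 arrays and at 9.36 on the WT array after H2O2 alone. No strain was measured more than 1 time in a condition, so the number of arrays limits the precision of every value below, and the p-values measure the spread between these arrays.

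The deleted genes and the marker came first, as a check of the labels. The slm9 probe set read log2 9.59 ± 0.31 in WT and 9.74 ± 0.04 in hip1D (SD, n = 4 arrays each), against 5.14 ± 0.22 in slm9D. The hip1 probe set read 9.51 ± 0.22 in WT, 9.63 ± 0.16 in slm9D and 8.39 ± 0.07 in hip1D, so that it fell by little more than 1 log2 unit in the deletion strain and stayed far above background. Whether it lies in the deleted part was not analysed here, and it checks that label only weakly. ura4, a uracil synthesis gene that replaced slm9 or hip1 in the mutants and is deleted at its own locus in all 3 strains, read 4.69 ± 0.41 in WT, 11.46 ± 0.25 in slm9D and 11.64 ± 0.20 in hip1D.

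**Figure D1:**
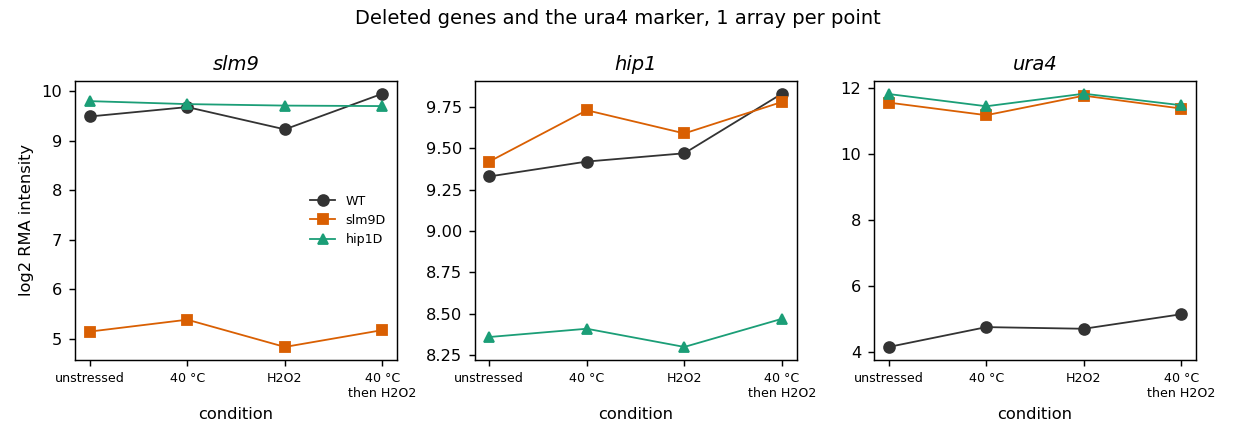
Log2 intensity (y axis) of slm9, hip1 and ura4 on each array by condition (x axis), with 1 point per array and lines joining the arrays of a strain. The slm9D arrays lie between 4.84 and 5.39 for slm9, the hip1D arrays between 8.3 and 8.47 for hip1, and the WT arrays between 4.16 and 5.15 for ura4.

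The next comparison asked whether the 2 deletions gave different transcript levels. Apart from slm9 (log2 difference slm9D minus hip1D -4.60 ± 0.12, SE) and hip1 (1.25 ± 0.09), only rpt6, a proteasome subunit gene, passed the test, at 0.65 log2 units lower in slm9D (-0.65 ± 0.06, adjusted p = 0.00111). These 3 of 2917 probe sets, 6 at an unadjusted p under 0.05, came from limma with 4 arrays per strain. Across genes, slm9D and hip1D arrays of the same condition correlated at 0.997 to 0.998, while WT and mutant arrays of a condition correlated at 0.928 to 0.959. These are correlations across genes, which are not independent replicates. A fit on the mutant arrays alone called 10 probe sets, and the meiosis and sporulation list passed the set test here (median -0.03, adjusted p = 0.0203, and adjusted p = 0.614 with an estimated correlation) with no member called.

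Mutants were then compared with WT over all conditions. Meiotic and sporulation genes were among the most raised transcripts in the mutants. The log2 differences were 4.75 ± 0.24 for meu7, 4.28 ± 0.28 for meu27, 3.73 ± 0.16 for rec10 (a component of meiotic linear elements), 3.42 ± 0.36 for spn6 (a sporulation septin) and 3.39 ± 0.16 for meu25 (mean ± SE, 8 mutant against 4 WT arrays). nmt1, a thiamine synthesis gene, was 5.22 ± 0.17 higher, and pma2, a plasma membrane proton pump gene, 4.77 ± 0.17 higher. mug137 and mug62 were not above background on any WT array and were at least 11.3-fold and at least 7.98-fold higher in the mutants, taking the background level as the lower bound. spn6, meu27, nmt1 and pma2 were below background on some but not all WT arrays, and their differences use the signals as measured there. The largest decreases, apart from slm9, were smaller. They included the pheromone gene mfm2 (-1.82 ± 0.23) and 3 other mating genes, byr1 (-1.39 ± 0.09), map1 (-1.16 ± 0.13) and ste4 (-1.14 ± 0.13), along with the serine synthesis gene ser2 (-1.42 ± 0.10).

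By list, 84 of 154 probe sets of meiosis and sporulation genes were higher in the mutants and 13 lower (85 and 14 adjusted over the list alone), with a median of 0.55 (set test adjusted p = 1.62e-08, and adjusted p = 0.57 with an estimated correlation). Quantile normalization repeated on S. pombe probe sets alone took that median to 0.08. Of 26 subtelomeric probe sets, 17 were higher and 5 lower (also 17 and 5 adjusted over the list alone), with a median of 0.78, among them isp3 (2.23 ± 0.18) and mal1 (1.42 ± 0.09); the adjusted p was 0.00366, and adjusted p = 0.461 with an estimated correlation. Members of the autophagy and vacuolar proteolysis list were higher in 16 of 23 cases and lower in 1 (17 and 1 adjusted over the list alone), with a median of 0.44. Among them were isp6 (0.89 ± 0.11), atg11 (1.12 ± 0.17) and sxa2 (1.46 ± 0.19), a mating protease gene that the list also holds. The adjusted p of the list was 0.000889, and adjusted p = 0.57 with an estimated correlation. Nuclear genes of oxidative phosphorylation went the other way, with 26 of 41 lower and 1, atp11 (0.76 ± 0.06), higher (27 and 1 adjusted over the list alone). Their median was -0.24 (-0.14 after quantile normalization on S. pombe probe sets alone), with qcr6 at -0.63 ± 0.05 and sdh1 at -0.52 ± 0.08 (adjusted p = 0.000245, and adjusted p = 0.57 with an estimated correlation). The nitrogen starvation and mating list, which holds map1 and ste4, had more members higher than lower in the mutants, with 16 of 29 higher and 5 lower (16 and 6 adjusted over the list alone). Its median was 0.60, or 0.11 after quantile normalization on S. pombe probe sets alone, with the hexose transporter gene ght5 at 1.69 ± 0.15 and isp4, an oligopeptide transporter gene, at 0.85 ± 0.09 (adjusted p = 0.0338, and adjusted p = 0.57 with an estimated correlation). Ribosome biogenesis genes were lower in 20 of 36 cases and higher in 4, the same numbers as adjusted over the list alone, with a median of -0.21, has1 at -0.47 ± 0.06 and utp5 at 1.03 ± 0.10 (adjusted p = 0.0052, and adjusted p = 0.57 with an estimated correlation).

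In all, 1575 probe sets differed between mutants and WT at an adjusted p under 0.05 in limma, 738 higher and 837 lower in the mutants. Of the 205 that differed at least 2-fold, 187 were higher and 18 lower, or 123 and 44 after quantile normalization on S. pombe probe sets alone. ura4 differed by 6.86 ± 0.17. Every mutant array carries that marker as well as a deletion, so the deletions and the marker are compared with WT together. The background level, the 95th percentile of the outside probe sets, was higher in WT than in both mutants in every condition. In WT, slm9D and hip1D it was 3.93, 3.76 and 3.76 unstressed, and 4.03, 3.78 and 3.8 after H2O2 alone. Control signals also moved with this grouping, the 3' minus 5' log2 difference of the RIP1 control being lower in WT than in slm9D and hip1D unstressed (0.90, 1.17 and 1.15), at 40 °C (0.86, 1.29 and 1.34), after H2O2 (0.89, 0.97 and 1.09) and after both (0.76, 0.85 and 1.01). The 28S rRNA control read 10.21 in WT, 10.73 in slm9D and 10.63 in hip1D unstressed, and 9.62, 10.3 and 10.61 at 40 °C, but 12.69, 12.89 and 12.83 after H2O2 and 13.4, 13.05 and 13.13 after both, so it did not keep 1 direction.

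Set against WT condition by condition, unstressed mutants had 759 higher and 1009 lower probe sets (913 and 806 after a shift to equal medians of the probe sets outside the S. pombe table). zym1, a metallothionein gene, was 3.08 ± 0.07 higher, inv1, the invertase gene, 3.21 ± 0.11 higher, and the subtelomeric genes mel1 and pcm2 were 2.43 ± 0.09 and 2.15 ± 0.09 higher. ste11, the transcription factor of mating, was lower (-1.68 ± 0.09). At 40 °C, 854 were higher and 995 lower. rds1, a stress gene, was then -2.78 ± 0.08 and tms1 -1.40 ± 0.07 relative to WT, while the histone genes hta2 and hhf2 were 1.42 ± 0.05 and 1.39 ± 0.05 higher. After 40 °C and then H2O2, 861 were higher and 864 lower, with htb1 at 1.41 ± 0.04 and eng1, a cell separation glucanase gene, at 1.45 ± 0.09. In these fits the single WT array of a condition is assumed to vary as the mutant arrays do (4 residual degrees of freedom).

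H2O2 alone gave the largest number of differences between mutants and WT, with 1108 probe sets higher and 1085 lower in the mutants, 374 and 76 of them at least 2-fold (213 and 134 after quantile normalization on S. pombe probe sets alone). All of these use the single WT array after H2O2, which had the lowest median of the 12 arrays (9.36) and the lowest correlation with the mutants of its condition (0.928 across genes with each). General stress genes were higher in the mutants in 28 of 32 cases and lower in 2 (28 and 2 adjusted over the list alone), with a median of 0.84. This list holds targets of the Sty1 MAP kinase and Atf1 and also pathway components such as sty1, wis1 and atf1. Some members, such as hsp16 and ctt1, are also on the heat shock or the oxidative stress list. The oxidant defence genes srx1 (sulfiredoxin) and ctt1 (catalase) were 1.80 ± 0.09 and 1.15 ± 0.05 higher. mel1 was 4.02 ± 0.09 higher and pcm2 3.44 ± 0.09. The adjusted p of the general stress list was 4.04e-07, and adjusted p = 0.57 with an estimated correlation. fus1, a mating formin gene, and rhp42, a DNA repair gene, were 4.19 ± 0.10 and 4.11 ± 0.09 higher in the mutants.

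At 40 °C, averaged over the strains, general stress genes rose in 17 of 32 cases and fell in 3 (17 and 3 adjusted over the list alone), with a median of 0.58 (adjusted p = 0.00232, and adjusted p = 0.623 with an estimated correlation). gld1, a glycerol dehydrogenase gene, rose by 2.77 ± 0.16 and mug14 by 3.26 ± 0.15 (log2 difference ± SE, n = 3 strains), and the stress genes fbp1 and cmk1 by 1.95 ± 0.22 and 1.22 ± 0.10. pcm2, lsd90 and tms1 rose by 3.38 ± 0.64, 3.11 ± 0.53 and 2.77 ± 0.55. They rose more in WT than in the mutants (mutants minus WT -2.34, -2.45 and -2.75). For pcm2 this came mostly from its higher level in unstressed mutants, given above, while tms1 was lower in the mutants at 40 °C (-1.40). The larger errors of pcm2, lsd90 and tms1 pool such strain differences over all 4 conditions. Of 22 genes of mitosis and cell separation, 15 fell and none rose (16 fell adjusted over the list alone), with a median of -0.86, including exg1 (-2.74 ± 0.18), adg2 (-2.68 ± 0.24) and slp1 (-2.33 ± 0.23). Their adjusted p was 9.48e-05, and adjusted p = 0.602 with an estimated correlation. Of 36 ribosome biogenesis genes 29 fell and 0 rose (29 adjusted over the list alone), with a median of -0.49 and gar1 at -1.08 ± 0.08 (adjusted p = 1.15e-07, and adjusted p = 0.57 with an estimated correlation). cdc22, which encodes the large subunit of ribonucleotide reductase, fell by 2.71 ± 0.16. Members of the autophagy and vacuolar proteolysis list rose in 17 of 23 cases and fell in 0 (19 rose adjusted over the list alone), with a median of 0.57 and atg22 at 1.02 ± 0.13 (adjusted p = 5.65e-06, and adjusted p = 0.57 with an estimated correlation). DNA repair genes rose in 15 of 29 cases and fell in 2 (16 and 2 adjusted over the list alone), with rad55 at 1.25 ± 0.12 (adjusted p = 0.000979, and adjusted p = 0.57 with an estimated correlation). limma called 662 probe sets higher and 750 lower at 40 °C, or 801 and 573 after the shift to equal medians outside S. pombe. The calls numbered 623 without slm9D, 637 without hip1D and 2179 without WT. The 18S rRNA control read 10.67 ± 0.21 unstressed and 10 ± 0.19 at 40 °C (SD, n = 3), and the 3' minus 5' difference of the CC338.15 control was 0.78 and 1.19 in WT, 0.97 and 1.43 in slm9D, and 0.99 and 1.56 in hip1D.

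H2O2 alone, averaged over the strains, raised pyp2 (2.76 ± 0.24), which encodes a phosphatase of Sty1, the kinase gene srk1 (1.90 ± 0.21), srx1 (2.23 ± 0.29) and ctt1 (1.64 ± 0.28). Of 29 oxidative stress and thiol redox genes, 12 rose and 4 fell (13 and 4 adjusted over the list alone), with a median of 0.21 (adjusted p = 0.00155, and adjusted p = 0.57 with an estimated correlation). Genes of G1/S transcription fell in 12 of 20 cases with none rising (13 fell adjusted over the list alone), with a median of -0.68, among them the S-phase cyclin gene cig2 (-2.20 ± 0.19) and the replication licensing gene cdc18 (-2.12 ± 0.20). Their adjusted p was 0.00381, and adjusted p = 0.57 with an estimated correlation. psu1, a cell wall gene, fell by 3.42 ± 0.09 and bms1, a ribosome biogenesis gene, changed by -1.60 ± 0.09. Of 41 oxidative phosphorylation genes 21 rose and 2 fell (22 and 2 adjusted over the list alone), with a median of 0.29 and cox17 at 0.85 ± 0.07 (adjusted p = 4.23e-06, and adjusted p = 0.57 with an estimated correlation). Control probe sets for ribosomal RNA also moved with H2O2, the one for the middle of the 28S rRNA reading 10.52 ± 0.28 in unstressed cells, 12.8 ± 0.10 after H2O2 and 13.19 ± 0.18 after 40 °C and H2O2 (SD, n = 3). The log2 signal of the 3' end of the ACT1 control minus that of its 5' end was 0.43 ± 0.04, 0.65 ± 0.01 and 0.91 ± 0.12 in the same order. limma called 460 higher and 852 lower, or 646 and 670 after quantile normalization on S. pombe probe sets alone. Without WT, slm9D or hip1D the calls numbered 2112, 415 and 558.

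After 40 °C and then H2O2, general stress genes rose in 23 of 32 cases and fell in 3 (23 and 3 adjusted over the list alone), relative to unstressed cells, with a median of 0.71. pyp2 rose by 3.51 ± 0.24, srx1 by 3.39 ± 0.29, fbp1 by 3.26 ± 0.22 and ctt1 by 2.51 ± 0.28 (adjusted p of the list = 2.08e-06, and adjusted p = 0.57 with an estimated correlation). Mitosis and cell separation genes fell in 19 of 22 cases, with none rising, the same as adjusted over the list alone, at a median of -1.28, including eng1 (-3.92 ± 0.39) and exg1 (-3.16 ± 0.18). Their adjusted p was 1.19e-05, and adjusted p = 0.57 with an estimated correlation. The licensing genes cdt1 and cdc18 fell by 3.94 ± 0.35 and 3.20 ± 0.20. These falls and rises went with the rRNA and ACT1 control signals given above. limma called 694 higher and 976 lower, with 1030 calls without slm9D, 1104 without hip1D and 2305 without WT.

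Cells that met H2O2 after the priming heat were then compared with cells given H2O2 alone. This comparison includes any lasting response to the heat itself, and whether heat changed the response to H2O2 was not tested. Averaged over the strains, mel1 (an alpha-galactosidase gene) rose by 3.50 ± 0.93, pcm2 by 2.64 ± 0.64, fbp1 by 2.10 ± 0.22 and mug14 by 1.94 ± 0.15. At 40 °C alone mel1, pcm2 and mug14 rose by 3.07, 3.38 and 3.26. cdt1 (-2.72 ± 0.35), exg1 (-2.12 ± 0.18), the phosphatase gene pho4 (-1.73 ± 0.18) and gln1, encoding glutamine synthetase (-1.83 ± 0.10), were lower. General stress genes rose in 14 of 32 cases and fell in 0 (16 rose adjusted over the list alone), with a median of 0.60 (adjusted p = 7.6e-05, and adjusted p = 0.597 with an estimated correlation). limma called 526 higher and 518 lower, or 651 and 414 after the shift to equal medians outside S. pombe, and the count moved with the arrays used. It was 438 with the 6 arrays of these conditions alone, 205 without slm9D, 331 without hip1D and 1825 without WT.

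Counts of changes of at least 2-fold were taken in each strain. From H2O2 alone to 40 °C then H2O2, 312 probe sets were at least 2-fold higher and 136 at least 2-fold lower in WT, against 34 and 24 in slm9D and 25 and 22 in hip1D. After quantile normalization on S. pombe probe sets alone these were 155 and 137 in WT, 32 and 33 in slm9D, and 22 and 30 in hip1D. For 40 °C alone these numbers were 168 and 112 in WT, 137 and 64 in slm9D, and 118 and 69 in hip1D (117 and 122, 116 and 85, and 124 and 89 after that normalization). H2O2 alone gave 49 higher and 296 lower in WT, 64 and 151 in slm9D, and 51 and 121 in hip1D. After that normalization the rises numbered 91 in WT, 91 in slm9D and 76 in hip1D. The larger number of falls in WT after H2O2 was lost after that normalization (115 in WT, 116 in slm9D and 90 in hip1D) and kept after the shift to equal medians outside S. pombe (293, 154 and 123). Each such count sets 1 array against 1 array, without replicates.

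**Figure D2:**
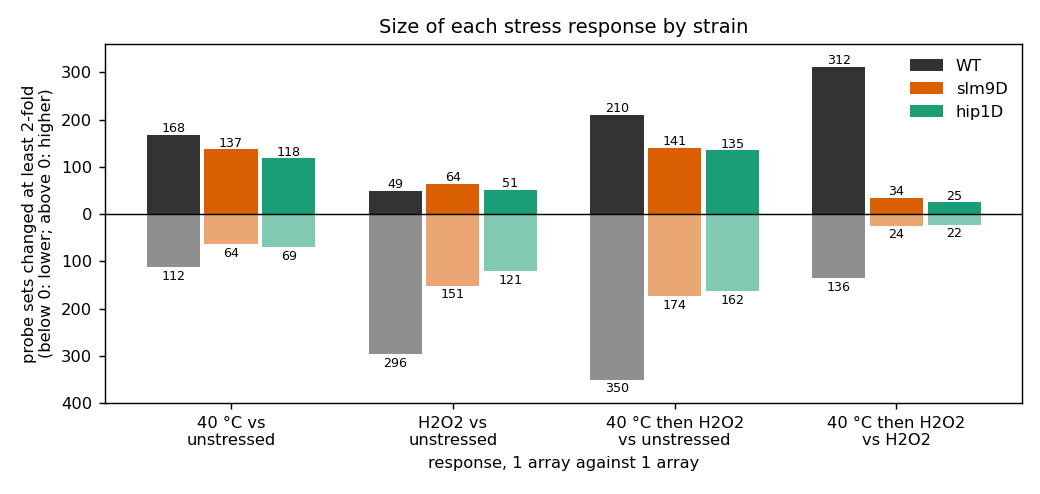
Number of probe sets changed at least 2-fold (y axis, higher above 0 and lower below 0) in each stress response (x axis) for WT, slm9D and hip1D, each bar from 1 array against 1 array. The bars of WT for 40 °C then H2O2 against H2O2 alone reach 312 and 136, and those of the mutants at most 34 and 24.

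The difference between the mutants' mean response and the WT response was tested as an interaction in limma. For the priming comparison, 876 probe sets responded less in the mutants, or more negatively, and 707 the other way. mel1 rose by 6.29 in WT and by 2.22 and 1.98 in slm9D and hip1D (interaction -4.19 ± 0.13, SE, adjusted p = 3.27e-14). The interactions of pcm2, ppk31 (a protein kinase gene), tms1, srx1, ssa1 (an Hsp70 chaperone gene) and ctt1 were -3.13 ± 0.13, -3.16 ± 0.12, -2.13 ± 0.09, -1.67 ± 0.10, -1.18 ± 0.05 and -1.16 ± 0.07. Of 32 general stress genes, 25 responded less in the mutants and 2 more (25 and 2 adjusted over the list alone). Their median response was 1.00 in WT, 0.40 in slm9D and 0.35 in hip1D (adjusted p = 3.96e-08, and adjusted p = 0.57 with an estimated correlation). Control signals differed between the strains in the same comparison, the 18S rRNA control going from 11.8 to 12.71 in WT, from 12.22 to 12.25 in slm9D and from 12.16 to 12.17 in hip1D. The 28S control went from 12.69 to 13.4, from 12.89 to 13.05 and from 12.83 to 13.13, and the 3' minus 5' difference of ACT1 from 0.66 to 1.03, from 0.65 to 0.89 and from 0.65 to 0.80. In the heat shock and chaperone list, 15 of 22 members responded less in the mutants and 2 more. These numbers were the same adjusted over the list alone. The adjusted p of the list was 0.000804, and adjusted p = 0.57 with an estimated correlation. In level, mutants minus WT, the general stress list had a median of 0.06 in primed cells after H2O2 and 0.84 after H2O2 alone. For the heat shock and chaperone list these medians were 0 and 0.27, and for the oxidative stress list 0 and 0.35. By these medians, primed mutants were close to primed WT. The smaller responses thus came mostly from higher levels in the mutants after H2O2 alone, which rest on a single WT array.

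The response to H2O2 alone uses the same WT array after H2O2 as the priming comparison but with the opposite sign, so opposite directions in the 2 comparisons are partly built in and are not separate evidence. It was higher in the mutants for 905 probe sets and lower for 475, though after quantile normalization on S. pombe probe sets alone the split was 518 and 560. rhp42 changed by -3.15 in WT and by 0.60 and 0.52 in slm9D and hip1D (interaction 3.71 ± 0.13). The interactions of fus1, sgo1 (encoding a meiotic shugoshin) and chs1 (encoding a chitin synthase) were 2.72 ± 0.14, 2.58 ± 0.15 and 2.38 ± 0.15. Those of srx1 and ctt1 were 1.35 ± 0.10 and 1.25 ± 0.07. Of the general stress genes, 19 of 32 responded more in the mutants and 2 less (20 and 2 adjusted over the list alone), with a median response of 0.02 in WT, 0.38 in slm9D and 0.36 in hip1D (adjusted p = 0.000209, and adjusted p = 0.57 with an estimated correlation). Across genes, the WT array after H2O2 alone correlated at 0.954 with unstressed WT and at 0.939 with primed WT after H2O2, while the arrays of slm9D and hip1D after H2O2 alone correlated at 0.958 and 0.964 with their unstressed and at 0.982 and 0.983 with their primed counterparts.

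To 40 °C alone, 662 probe sets responded more and 524 less in the mutants. mel1, zym1, tms1 and rds1 had interactions of -3.80 ± 0.13, -3.04 ± 0.09, -2.75 ± 0.09 and -2.04 ± 0.10. mel1 was higher in the unstressed mutants, as given above, and lower than in WT at 40 °C (-1.38 ± 0.09). zym1 already read 12.17 and 12.41 in the unstressed mutants against 9.21 in WT, and 13.38 to 13.45 in all 3 strains at 40 °C. nc-pho1, a non-coding RNA gene, had an interaction of 3.12 ± 0.08, falling by 3.26 in WT and by 0.10 and 0.19 in slm9D and hip1D. tlh2, a subtelomeric helicase gene with near-identical copies, has 4 probe sets with interactions of 2.55 ± 0.13, 2.84 ± 0.15, -0.02 ± 0.14 and -0.14 ± 0.43, of which the first 2 passed, so its change is uncertain. To 40 °C then H2O2, 781 responded more and 561 less, or 549 and 594 after quantile normalization on S. pombe probe sets alone. eng1 and adg1, both cell separation genes, had interactions of 2.37 ± 0.13 and 2.23 ± 0.10 there. That of cdt1, 1.42 ± 0.17, was 0.54 and no longer passed the test after the same normalization.

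**Figure D3:**
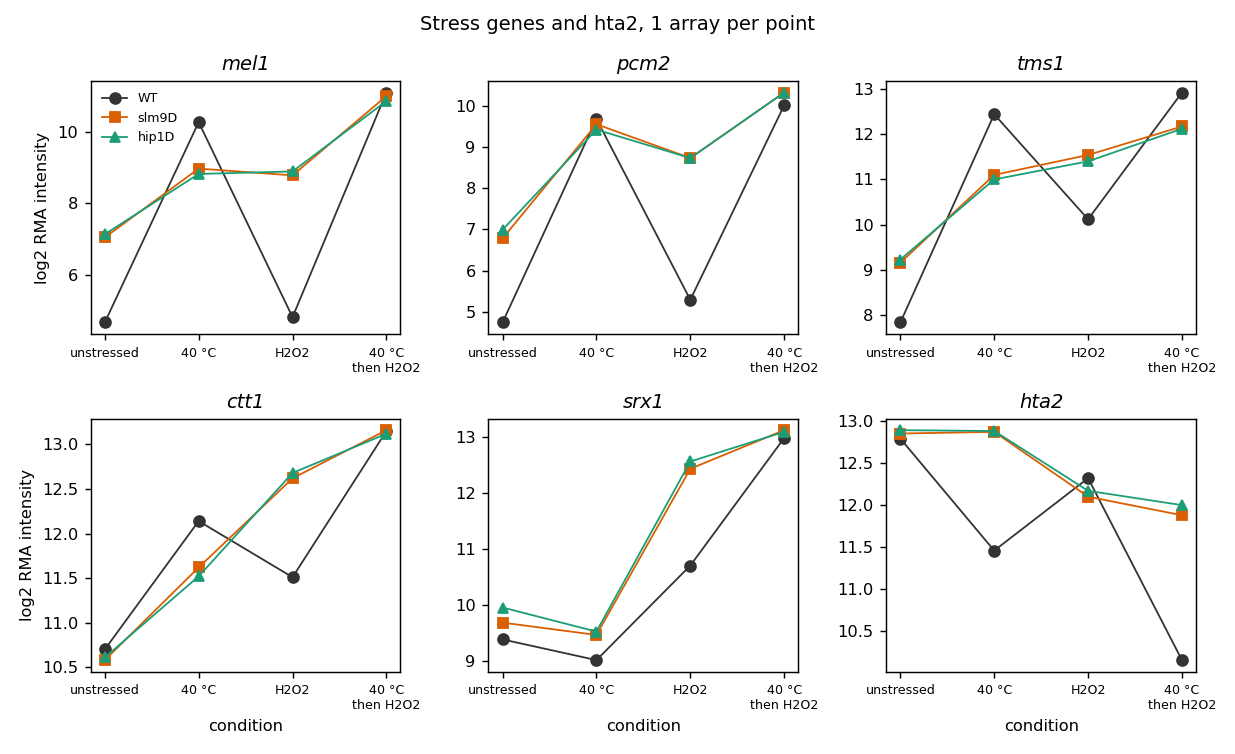
Log2 intensity (y axis) of mel1, pcm2, tms1, ctt1, srx1 and hta2 on each array by condition (x axis), with 1 point per array and lines joining the arrays of a strain. After H2O2 alone WT mel1 reads 4.81 and the mutants 8.78 and 8.89, and after 40 °C then H2O2 the readings are 11.1 in WT, 11 in slm9D and 10.86 in hip1D.

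Responses of the core histone list separated WT from the mutants in every comparison that included heat. At 40 °C, all 15 histone probe sets had a higher response in the mutants than in WT, also when adjusted over the list alone. The median response was -0.62 in WT, 0.03 in slm9D and 0.06 in hip1D. The interactions of hta2 (histone H2A), hhf2 (H4) and htb1 (H2B) were 1.34 ± 0.07, 0.99 ± 0.07 and 0.94 ± 0.06. The list also holds cnp1 (centromeric H3), pht1 (H2A.Z) and the histone gene regulator ams2. In unstressed mutants all of these read lower than in WT, and at 40 °C their levels were close in all strains. cnp1, for example, read 7.18 in WT, 6.52 in slm9D and 6.51 in hip1D unstressed, and 7.73, 7.57 and 7.6 at 40 °C. The list's median difference in level, mutants minus WT, was -0.16 unstressed (-0.02 after quantile normalization on S. pombe probe sets alone) and 0.61 at 40 °C. The responses of the 15 probe sets to 40 °C then H2O2 differed in the same direction, with medians of -1.06, -0.10 and -0.06 in WT, slm9D and hip1D. The adjusted p of the list was 9.95e-11 at 40 °C and 1.16e-09 after 40 °C then H2O2, and adjusted p = 0.419 with an estimated correlation in both. From unstressed cells to 40 °C then H2O2 the 28S control went from 10.21 to 13.4 in WT, from 10.73 to 13.05 in slm9D and from 10.63 to 13.13 in hip1D. The 18S control went from 10.5 to 12.71, from 10.9 to 12.25 and from 10.6 to 12.17, and the 3' minus 5' difference of ACT1 from 0.39 to 1.03, from 0.45 to 0.89 and from 0.46 to 0.80. After H2O2 alone the histone medians were -0.18, -0.17 and -0.20. Copies of the H3 and H4 genes are near-identical, so a value of a single copy is uncertain. Mitosis and cell separation genes likewise responded more negatively in WT at 40 °C, with 16 of 22 higher and 0 lower in the mutants (16 adjusted over the list alone), and medians of -1.09 in WT and -0.70 in both mutants (adjusted p = 2.11e-05, and adjusted p = 0.57 with an estimated correlation).

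**Figure D4:**
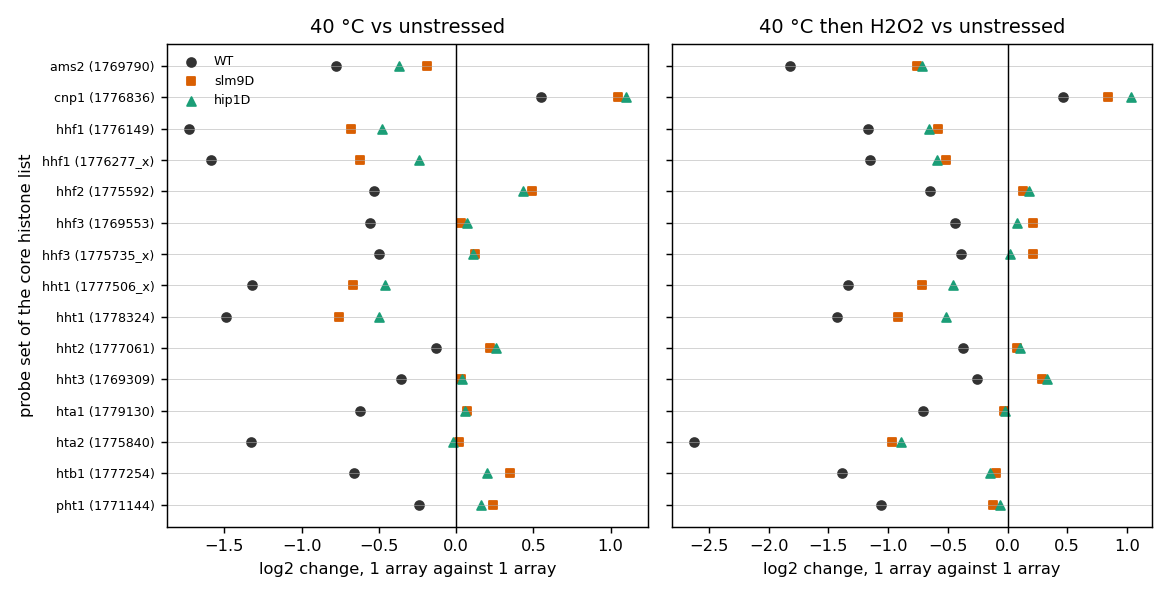
Log2 change (x axis) of each probe set of the core histone list (y axis) from unstressed cells to 40 °C and to 40 °C then H2O2, with 1 point per strain, each from 1 array against 1 array. All 15 WT points lie to the left of the 2 mutant points in both panels.

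The interaction tests rest on the spread between slm9D and hip1D and on a single WT array per condition (3 residual degrees of freedom), so a fault of a WT array would enter each comparison that uses it, and comparisons that share a WT array share its error.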

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

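Of the tests below, those for cross-hybridisation, fewer S-phase cells, RNA degradation, weaker exposure, the signal floor and the ura4 marker were chosen only after the result was seen, and the others were written before their values were seen.

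The results listed here differ between the mutants and WT in the size of a response, tested as an interaction in limma. The number of such probe sets was 1186 for 40 °C, 1380 for H2O2 alone, 1342 for 40 °C then H2O2, and 1583 for 40 °C then H2O2 against H2O2 alone. At the preset correlation the gene lists with such a difference numbered 7, 5, 8 and 14 in the same order, and none with an estimated correlation.

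For 40 °C the differences of the mutants' response from that of WT were 3.12 for nc-pho1, 2.55 for tlh2 (its other probe sets gave 2.84, -0.02 and -0.14, so its change is uncertain), 1.34 for hta2, 0.99 for hhf2, 0.94 for htb1 and 1.37 for adg1. They were -3.80 for mel1, -3.04 for zym1, -2.75 for tms1, -2.98 for ppk31 and -2.04 for rds1. Of these genes, mel1 and zym1 were already higher in the unstressed mutants. For H2O2 alone the differences were 3.71 for rhp42, 2.72 for fus1, 2.58 for sgo1, 2.38 for chs1, 1.25 for ctt1, 1.35 for srx1, -1.16 for mug16 (a gene of the meiosis list) and -1 for zym1.

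For 40 °C then H2O2 against unstressed cells the differences were 2.37 for eng1, 2.23 for adg1, 1.42 for cdt1, 1.70 for hta2, -2.91 for zym1 and -2.59 for mel1. Those of zym1 and mel1 came mostly from higher levels in the unstressed mutants. Against H2O2 alone the differences were 2.81 for fip1 (an iron permease gene), 2.54 for adg1, 1.97 for hta2 and 1.90 for cdt1. The negative ones were -4.19 for mel1, -3.13 for pcm2, -3.16 for ppk31, -2.53 for fus1, -2.13 for tms1, -1.67 for srx1, -1.16 for ctt1 and -1.18 for ssa1.

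Outside the named genes, 157 probe sets without a gene name were at least 2-fold higher in the mutants over all conditions. A probe set shared by 11 copies of the Tf2 retrotransposon was higher in the mutants by 1.78 ± 0.27 (SE, adjusted p = 0.000555). These were set apart because no single gene can be given to them.

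The higher histone response of the mutants at 40 °C was not limited to the H3 and H4 genes, since the probe sets of htb1, pht1, hta1, hta2, cnp1 and ams2 had a median of 0.61. However, hta1 and hta2 are both H2A genes, so they cannot test cross-hybridisation between copies. The values of pht1, cnp1 and ams2 came mostly from lower unstressed levels in the mutants. Cross-hybridisation between copies is therefore argued against for htb1 (0.94) alone and stays open for the others. Rescaling the arrays left a list median of at least 0.66, which argues against scaling. Fewer cells in S phase in the heated WT sample stay open, since the G1/S list moved the same way by a median of 0.20, less than the histones but above 0.

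For the higher stress gene response of the mutants to H2O2 alone, an exchange of the WT unstressed and H2O2 samples is argued against by a median WT change of 0.65 for the genes that H2O2 raised at least 2-fold in both mutants. Rescaling left a list median of at least 0.44, which argues against scaling. Degraded RNA in the WT sample stays open, since the mean 3' minus 5' difference of 4 control genes rose from unstressed cells to H2O2 by 0.05 in WT and by 0.02 and 0.08 in the mutants (WT minus mutants 0 ± 0.09, SE). A weaker exposure of the WT sample also stays open, since falls of at least 2-fold numbered 296 in WT against 151 and 121 in the mutants as deposited, and 293 against 154 and 123 after the shift to equal medians outside S. pombe, both of which go against it, but 115 against 116 and 90 after quantile normalization on S. pombe probe sets alone. Other faults of the single WT sample were not tested.

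The excess of raised genes among differences of at least 2-fold held among probe sets with WT and mutant means above log2 8. There 84.4% of 77 were higher (95% interval 74.4 to 91.7), which argues against a floor of dim signals for those probe sets. Among the other calls 122 were higher and 6 lower, and a floor stays open there. The interval treats probe sets as independent though they share arrays, and only the deposited scaling was used. The marker ura4, higher by 6.86, is in both mutants and not in WT, so these samples cannot tell its effect from that of the deletions.

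The arrays were also split in other ways with the same sizes. For mutants against WT over all conditions, 1 of 100 splits, the real one, had as many calls (1575, highest other 969). Every other split mixed WT with mutant arrays, so fewer calls were likely beforehand. The result says only that the calls follow the WT label, and it cannot tell the deletions from other differences of the WT strain or culture. For slm9D against hip1D, 4 of 35 had as many as the real 3. The highest other, 507, set the unstressed and H2O2 arrays of both mutants against their heated arrays. With condition as a term, that split compares the mutants' difference from WT without heat with their difference from WT after heat. It thus restates the differing responses to heat given above and is not separate evidence. For the 4 stress responses there were only 10 splits each, too few, and 1 of them, the real one, had as many calls (1412, 1312, 1670 and 1044, with 0 as the highest other).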

How the results depend on the processing

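Leaving out the WT array after H2O2 alone was chosen only after the result was seen. Of 163 gene values, each with 2 rescalings of the arrays, 1 was weaker, the interaction of cdt1 for 40 °C then H2O2 (0.54 in place of 1.42), and none turned its direction. Of 151 alternative counts, 121 stayed within 1.5 times. Counts at a 2-fold threshold were smaller by construction: mutants against WT 205 over all conditions, 191 unstressed, 212 at 40 °C, 450 after H2O2 and 186 after 40 °C then H2O2. The responses over the strains gave 185 (40 °C), 200 (H2O2), 358 (40 °C then H2O2) and 106 (against H2O2 alone), and the interactions 100, 153, 143 and 250 in that order. slm9D against hip1D gave 10 in a fit of the mutant arrays alone. Without a strain term the calls were 794 for 40 °C, 745 for H2O2 and 454 for 40 °C then H2O2 against H2O2 alone, and 438 for the last with only its 6 arrays, which has fewer residual degrees of freedom. Leaving out 1 strain gave 623 to 2179 for 40 °C, with the highest without WT, and 415 to 2112 for H2O2, 1030 to 2305 for 40 °C then H2O2 and 205 to 1825 for the last comparison, in each case the lowest without slm9D and the highest without WT. The fit has no term for responses that differ between strains, so differences between WT and mutant responses count as residual spread when WT is kept. How far this explains the counts was not tested. Leaving out 1 condition gave 1267 to 1399 for mutants against WT over all conditions, and strain as a random block 2348 (block correlation -0.262). Without the WT array after H2O2 alone it was 1437. Gene lists with an estimated correlation gave 0. Other causes were not tested.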

Other observations

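Iron uptake genes were higher in the mutants at 40 °C. All but 1 of the 11 list members, 10, were higher and 0 lower, the same as adjusted over the list alone, with a median of 0.82. fip1, an iron permease gene, was 1.49 ± 0.10 higher, and str3, a siderophore transporter gene, at least 7.65-fold higher, with the WT signal at background (adjusted p of the list 0.000498, and adjusted p = 0.57 with an estimated correlation). Their median response to 40 °C was -1.03 in WT, -0.11 in slm9D and -0.08 in hip1D.

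The 3 phosphate acquisition probe sets all had a higher response to 40 °C then H2O2 in the mutants than in WT. The median was 0.87, and all 3 also passed when adjusted over the list alone (adjusted p = 0.57 with an estimated correlation). In level, mutants minus WT, their median was -0.42 unstressed and 0.04 after 40 °C then H2O2, so the mutants started lower and did not end clearly higher. Of 2217 probe sets without a gene name above background, 538 were higher and 663 lower in the mutants over all conditions, 157 and 25 of them at least 2-fold.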
